A study of Mus musculus with 4 samples.

How the data were processed

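Lamin B1 DamID was measured in AML12 cells, a mouse hepatocyte line, on 4 two-colour Agilent arrays. DamID marks DNA that comes close to a chosen protein: a bacterial adenine methylase, Dam, is fused to that protein, and fragments carrying its methylation mark are amplified and compared with fragments from cells that express Dam alone. Per the labels, cells received a lentivirus carrying a control short hairpin RNA (shCtrl) or one against Topors (shTopors) and were collected 5 days later. Virus for Dam or the Dam-LaminB1 fusion was added 48 hours after plating and genomic DNA was isolated 72 hours after that. On every array the Dam-LaminB1 DNA carried Cy5 and the Dam-only DNA carried Cy3, per the labels' protocols, so no dye swap separates a dye effect from lamina contact. A dye effect shared by all arrays cancels in the difference between groups.

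The deposited table holds 1 value for each of 974016 array features and 4 arrays. It gives a signed log ratio of the 2 channels, made with Agilent Feature Extraction per the submitters' processing notes. The software version, background correction, dye correction, any smoothing and the genome build are not given in the sources used here. The base of the logarithm is not stated and no scanner file was used to find it, so sizes are given in log-ratio units and no fold is printed. The direction, Dam-LaminB1 over Dam-only, is likely rather than settled: it rests on the dyes in the labels and on the software's usual red-over-green ratio. The deposited medians per array were 0 and -0.0045 in shCtrl replicates 1 and 2 and 0.041 and 0 in shTopors replicates 1 and 2, so the arrays had not all been centred on their median. Between 7536 and 15778 features per array are exactly 0.

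Features are numbered and carry no probe name, gene or position here, and the gene table at hand pairs no feature number with a gene. Neighbouring numbers do not share signal: the correlation of consecutive features was 0.0046 to 0.0094 per array, so the numbers do not follow the genome. For this reason 5 planned results were not run: genes changed, changed windows of the genome, the cover of lamina domains, the shift of 24 gene lists and the lamina level of those lists. Those lists, and the Topors locus, are not analysed here.

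Each array was centred on its median. DamID is a ChIP-like measurement in which many features carry signal, so no loess or quantile step was part of the main analysis. Single features were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, shTopors minus shCtrl, all 4 arrays, no replicate block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Group differences in values per array were tested with a two-sided exact permutation test. With 2 arrays against 2 this test cannot give a p below 0.333. Correlations between arrays were computed across features, which are not independent replicates, so they carry no p. To relate the difference to the lamina ratio in control cells, features were ranked into 10 bins in 1 shCtrl array and the difference was taken against the other, for both choices and both shTopors arrays. The slope of the shTopors bin means on those of the shCtrl array not used for ranking was fitted by least squares. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

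The rule for named features was set before the data were examined, as were the tests and most alternatives: with no gene names, the 10 features with the smallest p in each direction, among those whose shTopors arrays lie on one side of both shCtrl arrays. Of these, 2 per direction are printed by number. The alternatives were the replicate number as a block, scaling by the median absolute deviation, quantile normalization, no centring, a trended and robust variance, leaving out the outer 0.1% of values of any array, 5 bins, Spearman's rho, the median absolute deviation as the measure of spread, and leaving out each array in turn. Leaving out features at exactly 0, removing the median of each of 912 layout columns, and leaving out arrays in the correlation and level results were added after seeing the data.

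The limma script was tested on simulated data with the features, levels and fitted spread of the shTopors against shCtrl comparison. With no changed feature it made 0 calls. With 50000 of 974016 features changed it called 92.6% of them at a change of 2 log-ratio units and 99.2% at 3 units, but 0% at 1 unit. With 200 changed features it called 0% at 1, 2 and 3 units. The number of arrays limits the precision: the median standard error of a feature's difference was 0.28 log-ratio units and the median margin of its 95% confidence interval was 0.66 either way.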

Results

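The contact of the genome with lamin B1, a filament protein lining the inner face of the nuclear envelope, was profiled in AML12 hepatocytes. The cells had received a control hairpin or one against Topors. The level of Topors is not measured in the data used here, so knockdown below stands for receipt of the Topors hairpin. TOPORS is a nuclear RING-domain protein with ubiquitin and SUMO ligase activity. The design compares 2 arrays from shCtrl cells with 2 arrays from shTopors cells, and asks whether knockdown of Topors changes which parts of the genome lie at the lamina. Each array gave a log ratio of Dam-LaminB1 over Dam-only DNA for 974016 features, and a higher ratio stands for more lamina contact if the ratio runs in the likely direction. The labels call the arrays of a group replicates without saying whether they came from separate cultures, so the p-values measure only the spread between these arrays. Features have no gene name or position here, so groups of features are described by their lamina ratio and not by gene.

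The overall width of the lamina profile was about equal in control and knockdown cells. The SD of the centred log ratios was 0.643 ± 0.0086 (SD, n = 2) in shCtrl and 0.645 ± 0.021 (SD, n = 2) in shTopors. The difference of 0.0020 was smaller than the spread between replicates (exact permutation test, two-sided, p = 1). Its sign turned when a single array was left out, to -0.0040 without shCtrl replicate 2 and to -0.012 without shTopors replicate 2. The interquartile range was 0.898 ± 0.039 in shCtrl and 0.926 ± 0.028 in shTopors (SD, n = 2, exact permutation p = 0.667).

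In the tails of the profile no difference between the groups could be told from chance with 2 arrays each. Features far below the array median, by more than 1 log-ratio unit, made up 4.24% ± 0.20 of shCtrl arrays and 5.29% ± 0.092 of shTopors arrays (SD, n = 2). Both shTopors arrays lay above both shCtrl arrays, which gives the smallest p the design allows (exact permutation test, two-sided, p = 0.333). The share of features more than 1 unit above the median was 7.80% ± 0.68 in shCtrl and 7.37% ± 2.2 in shTopors, a difference within the replicate spread (exact permutation p = 1). Skewness was 0.323 and 0.282 in shCtrl replicates 1 and 2, against 0.023 and 0.163 in shTopors replicates 1 and 2 (exact permutation p = 0.333). As deposited, before centring, 48.9% ± 1.0 of features in shCtrl and 51.0% ± 2.0 in shTopors lay above 0 (SD, n = 2, exact permutation p = 0.333).

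**Figure D1:**
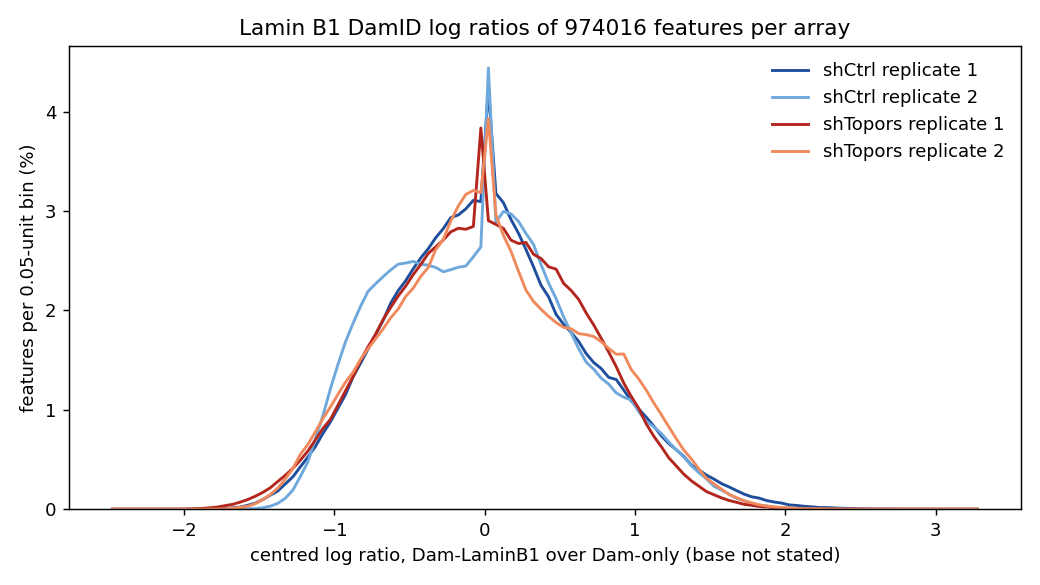
Distribution of centred log ratios (x axis, log-ratio units, base not stated) as the percentage of 974016 features per bin of 0.05 units (y axis), with 1 line per array. The 4 arrays have similar widths, with SDs of 0.649 and 0.637 in shCtrl and 0.630 and 0.659 in shTopors, and the narrow peak in the centre of each line holds the features listed as exactly 0.

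The lamina profiles of control and knockdown cells were positively correlated. Across features, Pearson's r was 0.720 between the shCtrl arrays and 0.700 between the shTopors arrays. Between groups it ran from 0.633 to 0.751, and the highest value of all was between shCtrl replicate 1 and shTopors replicate 1. The mean r was 0.710 within groups (2 pairs) and 0.680 between groups (4 pairs), a difference of 0.030. This difference moved with every array left out: it was -0.014 without shCtrl replicate 2, 0.015 without shTopors replicate 2, 0.055 without shCtrl replicate 1 and 0.064 without shTopors replicate 1.

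The features with the highest and lowest log ratios were shared between arrays well above chance, within and between groups. With no dye swap, a dye effect common to all arrays could be shared in the same way. Of the 10% of features with the highest ratio in 1 array, 48.9% to 54.2% were in the highest 10% of the other array of its group, and 44.8% to 57.2% in that of an array of the other group, against 10% by chance. For the lowest 10% these shares were 42.3% to 48.3% within groups and 41.7% to 47.6% between groups. The between-group range enclosed the within-group range for the highest features, and overlapped it for the lowest.

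No single feature changed in lamina ratio at the threshold. Of 974016 features, 0 passed an adjusted p of 0.05 in limma (Benjamini-Hochberg, smallest adjusted p = 0.629). At an unadjusted p under 0.05, 66098 features were found, or 6.79%, where 48701 would be expected with no change. Of these, 43809 had a higher ratio in shTopors and 22289 a lower one. In splits chosen after the data were seen, replicate 1 arrays against replicate 2 arrays gave 52534 features. Pairing shCtrl replicate 1 with shTopors replicate 2 against the other arrays gave 33596. The number expected with no change is therefore no firm reference for these arrays. Without shCtrl replicate 2 the higher features numbered 28296 and the total 47489, and without shTopors replicate 2 the total was 48553, both totals being below the number expected with no change. Without shCtrl replicate 1 the total rose to 75070 and without shTopors replicate 1 to 78575.

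The differences of single features had an SD over features of 0.38 log-ratio units. Their median standard error was 0.28, but a median of standard errors and an SD over features are unlike measures, so the gap is not a measure of change. The difference between the 2 single arrays of a group had an SD over features of 0.481 in shCtrl and 0.500 in shTopors. Much of the 0.38 can therefore be replicate spread. The quartiles of the difference over all features were -0.23 and 0.23 log-ratio units, with a median of -0.02, a 5th percentile of -0.56 and a 95th percentile of 0.69. The 95% confidence interval of a feature's own difference reached 0.66 either way in the median. In 16.6% of features both shTopors arrays lay above both shCtrl arrays, and in 20.4% both lay below, against 16.7% in each direction by chance. In simulated data of the same size and spread, 92.6% of 50000 features changed by 2 units were called, while 0% were called after changes of 1 unit in 50000 features or of up to 3 units in 200 features. Changes of those smaller or rarer kinds were not detectable with 2 arrays per group.

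None of the features with the smallest p passed the adjusted threshold. These features were picked by p from all those tested, and p-values this small are expected among that many features with no change. Their sizes can therefore come from chance and selection. Among the 10 with the smallest p and a higher ratio in shTopors, differences ran from 1.99 to 2.31 log-ratio units. The unadjusted limma p of these 10 ran from 2.4e-05 to 7.1e-05. Feature 910909 had a mean ratio of -1.21 in shCtrl and 1.09 in shTopors, a difference of 2.30 ± 0.25 (SE, n = 2 per group, limma adjusted p = 0.629). Feature 756594 went from a mean of -0.95 to 1.32, a difference of 2.26 ± 0.26 (SE). Among the 10 with the smallest p and a lower ratio, sizes ran from 1.88 to 2.23, with unadjusted limma p from 3.9e-05 to 1.2e-04. Feature 225028 had means of 1.43 in shCtrl and -0.73 in shTopors, a difference of -2.17 ± 0.25 (SE, limma adjusted p = 0.629). Feature 660977 had means of 0.77 and -1.32, a difference of -2.08 ± 0.26 (SE).

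Features with a high ratio in control cells did not lose or gain signal in a way that held for every pair of arrays. In the 10% of features with the highest control ratio the difference, shTopors minus shCtrl, averaged -0.05 ± 0.11 log-ratio units (SD over the 4 array combinations). Its sign followed the control array it was taken against. Against shCtrl replicate 1 it was -0.18 for shTopors replicate 1 and -0.10 for shTopors replicate 2, while against shCtrl replicate 2 it was 0.04 and 0.05. In the 10% with the lowest control ratio the difference averaged 0.05 ± 0.04 and was above 0 in 3 of the 4 combinations, the lowest being -0.0037. If the ratio runs the other way, this bin holds the strongest lamina signal and its difference is a lower signal in shTopors in those 3 combinations. The slope of the shTopors arrays on the control level averaged 0.947 ± 0.067 (SD over 4 combinations). The slopes were 1.03 and 0.972 against shCtrl replicate 2, and 0.889 and 0.896 against shCtrl replicate 1. A slope does not measure range alone, since it also depends on how well an array correlates with the array used for ranking. Against shCtrl replicate 1, shTopors replicate 2 had a slope of 0.896 although its SD was the wider, 0.659 against 0.649. The differences in the bins depend on these correlations too. The 4 combinations reuse the same 4 arrays and are not independent, so no test was made.

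**Figure D2:**
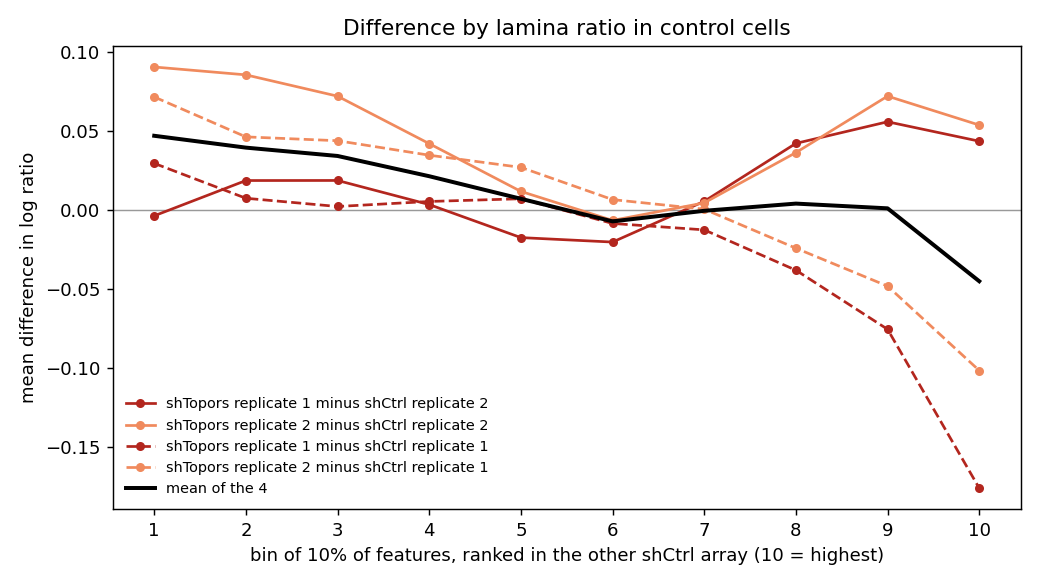
Mean difference in log ratio between a shTopors array and a shCtrl array (y axis, log-ratio units) in bins of 10% of features ranked in the other shCtrl array (x axis, bin 10 the highest), with 1 thin line per array combination and the mean of the 4 in black. In the highest bin the lines part by control array, from -0.18 to 0.05, and the mean is -0.05.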

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

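The number of features past the adjusted threshold was 0 in all 12 alternatives of the limma test, with smallest adjusted p-values from 0.564 to 0.995. The labels do not say that same-numbered arrays belong together, and 2 pairs are too few to decide it from their deviations (r = 0.077). With the replicate block 0 features passed, with 47498 higher and 25311 lower at an unadjusted p under 0.05. Apart from the leave-one-out fits, the alternatives gave 41784 to 47498 higher and 18821 to 25311 lower features. Leaving out 1 array at a time gave 28296 to 54607 higher and 17049 to 25889 lower features. The lowest higher count, without shCtrl replicate 2, fell by over 1.5 times. Leaving out an array assumes that the lone array of its group varies like the others. The difference in SD between groups ran from -0.012 to 0.017 with 1 array left out and turned negative without shCtrl replicate 2 or shTopors replicate 2, it was 0.00034 with zeros left out and 0.0026 with column medians removed, and the difference in median absolute deviation was 0.016. The excess of within-group over between-group correlation ran from -0.014 to 0.064 with 1 array left out, and was 0.030 to 0.033 otherwise. The slope on the control level was 0.926 to 0.949 under scaling, binning, layout and zero alternatives and 0.934 to 0.960 with a shTopors array left out. The differences in the highest and lowest bins of control level kept their signs under all 7 alternatives run, but their sizes moved: the highest was -0.02 without shTopors replicate 1 and -0.07 without shTopors replicate 2, and the lowest 0.08 and 0.01. No value exists for the slope or the bin differences with a shCtrl array left out, since they need both. The kept signs therefore do not test the dependence on the control array seen in the highest bin. The alternatives on genes, gene lists, windows and domains were not run, for want of names and positions. The number of arrays limits the precision, and signal over background was not analysed here.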

Other observations

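The fits with quantile normalization, without centring and with 1 array left out were planned before the data were examined, while the tests by level bins, on layout columns, on splits, on disjoint pairs of arrays and on exact zeros, and the reading of the ratio of higher to lower features, were chosen after the data were seen. The features with a higher ratio in shTopors at an unadjusted p under 0.05 were most frequent at intermediate to high mean ratios over the 4 arrays. If the ratio runs the other way, these are features with a lower ratio at intermediate to low mean lamina ratios. With features ranked into 10 bins by their mean over all 4 arrays, they made up 7.00% of bin 8 and 6.35% of bin 7, against 1.51% of the lowest and 1.69% of the highest. Features with a lower ratio made up 1.58% of the lowest bin, 2.95% of bin 9 and 2.34% of the highest. In the lowest and the highest bin the lower features outnumbered the higher ones, by 1542 to 1474 and by 2275 to 1642, while in each of the other bins the higher features were more frequent. The ranking uses the same arrays as the difference, so a feature that moves far between the groups lies nearer the middle of the ranking. The low shares in the end bins can come from this, and the bins do not show the level in control cells.

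The first pattern weighed is the surplus of higher over lower features at an unadjusted p under 0.05. Its ratio was 1.97, and 2.47 with no centring. Over the leave-one-out fits the ratio ran from 1.47 without shCtrl replicate 2 to 2.28 without shTopors replicate 1. Over all features the balance leaned the other way, with 47.0% of the differences above 0. In 20.4% of features both shTopors arrays lay below both shCtrl arrays, and in 16.6% above. The values argue against differences in width or shape between arrays as the whole cause. After quantile normalization the ratio was 1.73, against at most 1.37 in the splits that mix the groups after the same step. Over the leave-one-out fits it was 1.46 to 2.02, but no mixed split was fitted with an array left out. The values argue likewise against a trend across the columns of the array layout, in which column position took 0.165% to 0.597% of the variance of an array. With column medians removed the ratio was 1.83, against at most 1.42 in the mixed splits. Over the leave-one-out fits it was 1.46 to 2.15, again without a like fit of a mixed split. Of the 3 splits of the 4 arrays into pairs, 1, the real one, gave a ratio as large, the highest of the other splits was 1.47, and 3 splits are too few for a share under 0.05. Chance differences between arrays therefore stay open, since the splits cannot decide on them. A batch shared by the arrays of a group, for which the labels give no information, and the knockdown itself also stay open and were not tested.

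The second pattern is that part of the difference between a shTopors and a shCtrl array recurred between the other 2 arrays. The covariance of a shTopors minus shCtrl difference with that of the other 2 arrays was 0.034 when paired by number (r = 0.136). It was 0.016 when crossed (r = 0.057), on average 0.0248, or an SD of 0.158 log-ratio units of recurring difference. This average is fixed by the within-group and between-group covariances of the arrays. It restates on another scale the excess of within-group over between-group correlation, 0.030, and is not a separate observation. That excess ran from -0.014 without shCtrl replicate 2 to 0.064 without shTopors replicate 1, and the covariance needs all 4 arrays. After quantile normalization the mean covariance was 0.0252. That step keeps the order of features within each array and could hardly change a value fixed by array covariances, so it is a weak test of array shape. With column medians removed the mean covariance was 0.0247. Column position took at most 0.597% of the variance of an array, so a trend across layout columns is too small to account for it. Trends along rows or in 2 dimensions were not tested. The difference between replicate 2 and replicate 1 also recurred from one group to the other, with a covariance of 0.018 (r = 0.077), above that of the crossed pairing. The other pairing of replicate 2 with replicate 1 arrays, across the groups, gave -0.016 (r = -0.057). These values come from the same array covariances and are not separate observations. The same sum over the 3 splits of the 4 arrays is 0 by construction, so one split must come out highest. The hypothesis that small lamina changes spread over many features may follow the knockdown is therefore compatible with these values. So are a batch shared within each group and chance differences between arrays.

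The recurrence was stronger for rises than for falls. The 1% of features with the largest rise in one pair of arrays averaged 0.25 log-ratio units higher in the disjoint pair, with 0.17 to 0.33 over the 4 selections, and 58.8% to 66.8% of them were above 0 there, against 43.2% to 49.0% of all features. The 1% with the largest fall averaged -0.02 in the disjoint pair, with -0.09 to 0.09, and 44.0% to 57.7% of them were below 0 there. Set against the mean of all features in the same pair, the falls were -0.032 against 0.046, -0.090 against -0.026 and -0.035 against 0.0056. In the remaining selection they went the other way, 0.094 against 0.015. Differences between replicate 2 and replicate 1 of a group, selected in one group and measured in the other, averaged 0.02 for the largest rises. For the largest falls they averaged -0.11, so an uneven recurrence also appeared without the contrast between groups. After quantile normalization the rises averaged 0.24 and the falls -0.02. The selections reuse 4 arrays and were not tested.

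Exact zeros fell on the same features far more often than independent arrays would give: 1881 features were 0 on all 4 arrays, where 0.011 would be expected. They made up 1.02% and 1.62% of features in shCtrl replicates 1 and 2 and 0.912% and 0.774% in shTopors replicates 1 and 2 (exact permutation test, two-sided, p = 0.333).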
